A study of Mus musculus with 12 samples.

How the data were processed

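RNA of a striatal line with wild-type huntingtin (Q7) and of one with mutant huntingtin (Q111) was measured on 12 Affymetrix mouse arrays. There were 3 arrays for each of 4 groups: each line kept at 33 °C, and each line after 6 h at 42 °C. Total RNA was extracted with a column kit, per the labels' protocols. The deposited values are log2 levels per probe set made with RMA, which corrects background, normalizes quantiles and summarizes the probes of a set, per the submitters' processing notes. The RMA software, its version and the chip definition are not given in the sources used here. Arrays had similar but not identical distributions, with a largest gap of 0.49 between a quantile of an array and the mean over arrays, so levels were used as deposited and other scalings were tried.

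The table held 45101 probe sets, 64 of them controls. Of the rest 34945 named 1 gene, 932 named several and 9160 are unnamed here, and 34741 were matched by gene identifier. Probe sets naming several genes or none were left out. Each of 18193 genes was represented by the probe set with the highest mean over all arrays; 9010 genes had more than 1. Of the 5525 genes called for heat shock in Q7 cells 2543 had other probe sets above background range; for 1395 at least 1 of these did not pass, and for 166 at least 1 passed in the opposite direction. These numbers were 3412, 1644 and 359 of 8758 genes for heat shock in Q111 cells, 419, 360 and 0 of 1041 for the difference of effects, 704, 387 and 0 of 1962 for the lines at 33 °C, and 1719, 1065 and 29 of 4018 after heat shock. Hspa1a and Hspa1b are near-identical copies whose signals are uncertain as separate values. The 27 probe sets for bacterial RNA that was not added had a median of 2.85. Their highest value on any array, 5.14, served as the bound of background range. Scanner files were not used here, so probe-level background was not assessed, and the number of arrays limits precision.

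Groups, comparisons, tests, gene lists and most alternatives were chosen before the data were examined. limma fitted 4 group means to all 12 arrays (8 residual degrees of freedom, prior degrees of freedom 3.23) and tested 5 contrasts: heat shock in each line, the difference of these effects, and the lines at 33 °C and after heat shock. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and calls at an adjusted p under 0.05; changes of at least 2-fold were counted too. Gene lists were tested with camera (preset correlation 0.01), adjusted over the 22 gene lists or the 9 marker lists of a contrast. With an estimated correlation in its place, only the chaperone list in each line after heat shock and the neural progenitor markers at 33 °C kept their calls. The gene lists were cytosolic chaperones, TRiC and prefoldin, proteasome, ER chaperones and degradation, ATF4 and amino acid response, NRF2 response, autophagy and ubiquitin, cholesterol synthesis, S phase, mitosis, p53 targets, immediate early genes, extracellular matrix, actin cytoskeleton, ribosomal proteins, ribosome biogenesis, oxidative phosphorylation, PGC-1alpha and mitochondrial antioxidants, glycolysis and hypoxia, interferon response, histones, and BDNF and REST targets. The marker lists covered neurons, striatal projection neurons, neural progenitors, astrocytes, oligodendrocyte lineage, microglia and macrophages, endothelium, fibroblasts, and sex-linked genes. Of 726 listed genes 658 were measured.

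Genes named were the 6 with the largest positive and the 6 with the largest negative change for heat shock in each line and for the lines at 33 °C, among called genes whose arrays did not overlap between the groups; 8 and 8 for the difference of effects; 4 and 4 for the lines after heat shock; up to 3 members of each called list and of the chaperones in every comparison; and 8 genes fixed by name, 1 of which is not analysed here. Predicted genes and clone names were not named. Other genes named beside a small count or as list members were chosen after their values were seen.

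The replicate numbers come from the labels. Deviations from the group means correlated across genes between untreated arrays of the same number (r = 0.516, 0.402 and 0.577). The numbers may thus pair the untreated arrays of the lines. The labels do not say so, and r reached 0.588 between heat-shocked arrays of the lines with different numbers. Arrays of the other compared groups were not taken as paired. Replicates were not duplicates: replicate pairs held identical values in 10 to 60 probe sets, and the SD of their differences was 0.31 to 0.76.

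Alternatives were the mean of all probe sets or every probe set separately, the brighter genes alone, arrays centred on the median of genes or of ribosomal protein genes, a further quantile normalization, a variance trend with and without robust fitting, array weights, only the groups compared, the replicate number as a block, an adjusted p under 0.01, an estimated correlation and fry for lists, and each array left out. Chosen after seeing the data were: leaving out the heat-shocked array of each line that stood apart, the same with an estimated correlation, the BioB spike or the actin 3' minus 5' level as a covariate, and a block over the untreated arrays alone. Correlations across genes and overlaps of calls were described without p-values.

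The tests were checked on simulated data in which 200 of 18193 genes changed. Genes were drawn independently of each other from normal distributions. In the real data 5.72% to 48.14% of genes were called, so the shares recovered need not hold there. At 1.5-, 2- and 4-fold, 16.4%, 46.3% and 95.5% were recovered for heat shock in Q7 cells, and 4 of 109 calls were false. For heat shock in Q111 cells the shares were 9.0%, 41.8% and 90.9% with 2 of 96 calls false. For the difference of effects they were 0%, 10.4% and 62.1% with 4 of 52 false, for the lines at 33 °C 13.4%, 55.2% and 87.9% with 7 of 111 false, and for the lines after heat shock 10.4%, 47.8% and 92.4% with 5 of 105 false. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9 were used.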

Results

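STHdh cells are lines made from the striatum of embryonic mice that carry a knock-in huntingtin allele. The wild-type line, STHdhQ7/Q7 (Q7 cells here), has a short polyglutamine tract. The mutant line, STHdhQ111/Q111 (Q111 cells), has an expanded one, the kind of change that underlies Huntington's disease. Total RNA of each line was profiled on Affymetrix mouse arrays under growth at 33 °C and after 6 h at 42 °C. There were 4 groups of 3 arrays, 12 arrays in all, and 18193 genes were tested. The comparisons ask how each line responded to heat shock, whether the responses differed, and how the lines differed at each temperature. Values are log2 levels, differences are log2 differences with their standard error (SE), and levels are given as mean ± SD with n = 3 arrays per group. The number of arrays limits the precision. Nothing in the labels says that the replicates are separate cultures, so the p-values measure only the spread between these samples, which may be technical. Highest among probe sets for bacterial RNA that was not added was a level of 5.14, and levels at or under it are called background range here.

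Htt, which encodes huntingtin, was lower in Q111 than in Q7 cells at 33 °C, at 7.58 ± 0.25 against 8.87 ± 0.10 (difference -1.29, SE 0.17, adjusted p = 0.000265), and after heat shock (difference -1.15, SE 0.17, adjusted p = 0.000546). It fell after heat shock in Q7 cells (-1.01, SE 0.17, adjusted p = 0.000883) and in Q111 cells (-0.87, SE 0.17, adjusted p = 0.00147). These levels come from the brightest of 4 Htt probe sets and do not show the length of the repeat. Of the other 3, 1 at a mean level of 5.34 gave -1.11 and -0.84 for heat shock in Q7 and Q111 cells and -1.07 for the lines at 33 °C. Another, at 5.50, was 1.44 higher after heat shock in Q111 cells and gave -0.17 for the lines at 33 °C and 1.0 after heat shock, and the last, at 4.65, gave -0.48 and 0.02 for heat shock. With the mean of all Htt probe sets the heat shock value in Q111 cells was -0.06 (adjusted p = 0.792) and the difference between lines after heat shock was -0.26 (adjusted p = 0.33), so both calls rest on the choice of probe set. Over all alternatives the adjusted p of the first ranged from 0.000565 to 0.792 and that of the second from 1.16e-06 to 0.33.

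In Q7 cells heat shock raised the cytosolic chaperones, the proteins that hold or refold unfolded proteins. Hspa1a, the heat-inducible Hsp70, rose from 5.96 ± 0.37 to 11.45 ± 0.04 (change 5.48, SE 0.22, adjusted p = 4.06e-07). Hspb1, the small heat-shock protein Hsp27, rose by 3.44 (SE 0.15) and Dnaja4, a J-domain partner of Hsp70, by 2.97 (SE 0.17). Dnajb1, another such partner, rose by 1.24 (SE 0.13), Hsph1, an Hsp110 nucleotide exchange factor, by 0.90 (SE 0.14), and Hspa1b by 1.35 (SE 0.13). The Hspa1b probe set used here started at 11.93, and the other 2 Hspa1b probe sets gave 3.83 and 4.07; Hspa1a and Hspa1b are near-identical in sequence and their signals cannot be taken as separate. The Hsph1 and Dnajb1 probe sets used here are bright too, with means of 13.19 and 11.98, and the other probe set of each gave 2.89 and 2.21. Of 30 chaperone genes 24 rose and 1, Hspa4 (-1.25), fell, and 25 and 1 did so adjusted over the list alone. The median change was 0.95, camera gave an adjusted p of 2.24e-12, and adjusted p = 0.0164 with an estimated correlation. Hsf2, a heat shock transcription factor, was 0.89 (SE 0.31) higher, which missed the threshold (adjusted p = 0.0502).

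Targets of p53, the damage-responsive transcription factor, were higher after heat shock in Q7 cells: 16 of 23 rose and 0 fell, and 18 rose adjusted over the list alone. Eda2r and the death receptor gene Fas rose by 2.88 (SE 0.40) and 2.78 (SE 0.29), and Trp53inp1 by 2.31 (SE 0.40). The list had a median of 0.87 (camera adjusted p = 8.9e-09, adjusted p = 0.208 with an estimated correlation). Among 24 genes for chaperones and degradation in the endoplasmic reticulum 9 rose and 2 fell, the same counts adjusted over the list alone. Sdf2l1 rose by 2.24 (SE 0.29), Dnajb9 by 1.4 (SE 0.19) and the disulfide isomerase gene Pdia4 by 1.38 (SE 0.24), while Sel1l (-0.66) and Atf6 (-0.87) fell. The median was 0.31 (adjusted p = 0.00279, adjusted p = 0.369 with an estimated correlation). Of 21 autophagy and ubiquitin genes 9 rose, among them Atg12 (1.42, SE 0.17), Gabarapl2 (1.31, SE 0.14) and Atg5 (1.22, SE 0.20), and Wipi1 (-1.06) fell. The other 2 Atg5 probe sets, with means of 9.74 and 9.07, gave 0.45 and 0.26 and did not pass. Adjusted over the list alone these counts were 10 and 1, with a median of 0.28 (adjusted p = 0.00361, adjusted p = 0.369 with an estimated correlation).

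Genes for the extracellular matrix fell in Q7 cells: 30 of 35 were lower and 1, Col1a2 (0.83), was higher, and 31 and 1 adjusted over the list alone. The rise of Col1a2 rests on the choice of probe set, since one nearly as bright gave -0.03. Col8a1 fell from 10.59 ± 0.25 to 6.93 ± 0.65 (-3.66, SE 0.42), as did the basement membrane collagen gene Col4a2 (-2.55, SE 0.32) and Tnc, which encodes tenascin C (-2.5, SE 0.23). The list median was -1.18 (camera adjusted p = 6.53e-12, adjusted p = 0.192 with an estimated correlation). Cholesterol synthesis genes fell in 14 of 20 cases with 0 higher, 15 adjusted over the list alone. The list median was -0.93 (adjusted p = 4.5e-07, adjusted p = 0.256 with an estimated correlation). They included Mvk, mevalonate kinase (-1.94, SE 0.22), Nsdhl (-1.89, SE 0.17) and Srebf2, the regulator of the pathway (-1.55, SE 0.22). The other Mvk probe set gave -0.89. Actin cytoskeleton and focal adhesion genes fell in 18 of 36 cases and 1, Rhob (0.38), rose, 21 and 1 adjusted over the list alone. The median was -0.48 (adjusted p = 1.9e-06, adjusted p = 0.229 with an estimated correlation). Ankrd1 fell by 2.5 (SE 0.23), the filamin gene Flna by 1.71 (SE 0.19) and Myl9 by 1.68 (SE 0.40).

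Mitosis genes fell in Q7 cells in 16 of 29 cases with 0 higher, and adjusted over the list alone 17 fell and 1 rose. The proliferation marker Mki67 fell by 1.72 (SE 0.26), the kinase gene Plk1 by 1.57 (SE 0.19) and the cyclin gene Ccnb2 by 1.41 (SE 0.22). Their median was -0.62 (camera adjusted p = 2e-05, adjusted p = 0.369 with an estimated correlation). Ribosome biogenesis genes fell in 18 of 30 cases and 1, Nop16 (0.70), rose, 19 and 1 adjusted over the list alone. Examples were Wdr43 (-1.45, SE 0.13), nucleolin, Ncl (-1.39, SE 0.19), and Rrp12 (-1.37, SE 0.30). Their median was -0.67 (adjusted p = 4.15e-05, adjusted p = 0.38 with an estimated correlation). Immediate early genes, which growth and stress signals switch on within minutes, went both ways, with 9 of 26 higher and 6 lower (the same adjusted over the list alone), and were not called as a list (median 0.09, adjusted p = 0.207). Among them Fos rose by 2.64 (SE 0.20), Atf3 by 2.37 (SE 0.30) and Maff by 0.69 (SE 0.20). S phase genes went both ways too, 8 higher and 5 lower of 29 (8 and 7 adjusted over the list alone), and were not called as a list (median 0.20, adjusted p = 0.26).

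Apart from Hspa1a, the largest rises in Q7 cells were in Slc5a5, the sodium iodide symporter (4.64, SE 0.19), Klb, the co-receptor beta-Klotho (4.54, SE 0.29), the long non-coding RNA Sox2ot (4.48, SE 0.37), the phospholipase gene Pla2g4c (4.34, SE 0.23) and Efnb3, ephrin B3 (4.28, SE 0.32). Scara3 (-4.91, SE 0.32), the sodium/proton exchanger gene Slc9a9 (-4.21, SE 0.23), Sprr2h (-4.11, SE 0.30), Haghl (-4.08, SE 0.36), the RNA demethylase gene Fto (-3.92, SE 0.35) and Zc3h6 (-3.91, SE 0.36) fell most. Slc5a5, Sox2ot and Efnb3 before heat shock, and Scara3, Slc9a9, Sprr2h and Zc3h6 after it, were in background range, so these sizes are not firm. The other probe set of Slc5a5 (0.51) and of Pla2g4c (0.81) did not pass, nor did 1 of the other 3 of Haghl (0.20; the rest gave -4.24 and -4.72), and the second Gabarapl2 probe set fell (-0.50). In all, limma called 5525 genes at an adjusted p under 0.05, 2232 higher and 3293 lower, and 2948 of them changed at least 2-fold. Centring each array on the median of its genes adds 0.35 to every change in Q7 and 0.73 in Q111 cells, although the median change over genes was 0.0026 and -0.0182 as deposited. That centring turned the share of higher genes among those called from 40.4% to 70.1%. The share was 33.7% with ribosomal centring and 44.3% with a further quantile normalization. The actin control probe sets, whose 3' minus 5' signal grows as RNA is degraded or copied incompletely, went from 0.54 ± 0.16 to 1.48 ± 0.12 together with these gene groups. With that measure as a covariate, chosen after seeing the data, 436 genes were called, 252 higher and 184 lower, so that the share of higher genes was 57.8%. Over the 5525 genes the median size of the change went from 1.04 to 0.98 with the covariate, while the median SE rose from 0.21 to 0.43.

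In Q111 cells heat shock raised chaperones too. Hspa1a went from 5.95 ± 0.33 to 12.43 ± 0.26 (change 6.48, SE 0.22, adjusted p = 8.91e-08), Hspb1 rose by 3.95 (SE 0.15) to 13.64, where the highest level on an array averaged 14.46, and Dnaja4 rose by 3.34 (SE 0.17). Dnajb1 rose by 1.33 (SE 0.13), Hsph1 by 1.0 (SE 0.14) and Hspa1b by 1.49 (SE 0.13), and Hsf2 was 0.67 (SE 0.31) higher without passing the test (adjusted p = 0.096). The other probe sets gave larger rises, 3.48 for Hsph1, 2.45 for Dnajb1 and 4.03 and 4.43 for Hspa1b. Of the 30 genes 23 rose, 24 adjusted over the list alone, and 2 fell in either count, Hspa4 (-0.79) and the testis-enriched Hsp70 gene Hspa2 (-0.69). The median change was 0.97 (camera adjusted p = 4.65e-10, adjusted p = 0.0316 with an estimated correlation).

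Immediate early genes rose in Q111 cells in 13 of 26 cases and 1, Jund (-0.40), fell. Adjusted over the list alone 14 rose and 1 fell. Atf3 rose by 3.32 (SE 0.30), Maff by 2.40 (SE 0.20) and Fos by 2.40 (SE 0.20), and the list median was 0.65 (camera adjusted p = 0.000283, adjusted p = 0.467 with an estimated correlation). Of 23 p53 targets 14 rose, 15 adjusted over the list alone, and 3 fell, Sesn1 (-0.87), Plk2 (-0.36) and Tnfrsf10b (-0.93). Eda2r rose by 2.42 (SE 0.40), Trp53inp1 by 2.19 (SE 0.40) and the cyclin-dependent kinase inhibitor gene Cdkn1a by 1.59 (SE 0.25). Untreated Q111 replicate 1 was above the other untreated Q111 arrays for these genes, so their sizes depend on it. Eda2r was at 9.21 against 7.36 and 7.79, Trp53inp1 at 11.06 against 9.36 and 9.30, and Cdkn1a at 11.03 against 9.98 and 9.94. The list median was 0.68 (adjusted p = 0.00174, adjusted p = 0.583 with an estimated correlation). Oxidative phosphorylation genes rose in 23 of 57 cases and fell in 5, Ndufs1 (-0.54), Ndufs3 (-0.40), Ndufv1 (-0.68), Sdha (-0.33) and Atp5d (-0.34), with the same counts adjusted over the list alone. Cox7c rose by 1.83 (SE 0.23; its other probe set gave 0.85 and did not pass), Ndufa1 by 1.11 (SE 0.17) and Ndufb2 by 1.10 (SE 0.16). The median was 0.19 (adjusted p = 0.0019, adjusted p = 0.583 with an estimated correlation). Cytosolic ribosomal protein genes had a median of 0.11 and 5 of 30 rose, Rpl14 (1.51, SE 0.11), Rps25 (1.35, SE 0.17), Rps27 (0.84, SE 0.18), Rps6 (0.77) and Rpl22 (0.29), 4 adjusted over the list alone. That call (adjusted p = 0.0177, adjusted p = 0.583 with an estimated correlation) was lost when arrays were quantile normalized again (adjusted p = 0.089) or centred on these genes themselves (adjusted p = 0.0794); its alternatives ranged from 0.000209 to 0.583. With median-centred arrays 30 of 30 ribosomal protein genes were higher (median 0.84), as were 53 of 57 oxidative phosphorylation genes with 0 lower (median 0.92).

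Interferon response genes fell in Q111 cells after heat shock: 16 of 26 were lower and 0 higher, the same counts adjusted over the list alone. Oasl2 fell from 8.01 ± 0.69 to 4.83 ± 0.13, in background range, and the guanylate-binding protein gene Gbp3 (-2.87, SE 0.41) and Ifit3 (-2.30, SE 0.24) fell. The median was -1.21 (camera adjusted p = 0.000153, adjusted p = 0.583 with an estimated correlation). With median-centred arrays 13 interferon genes were lower and 6 higher, at a median of -0.49, and the list kept its call. Extracellular matrix genes fell in 26 of 35 cases and 1, the proteoglycan gene Dcn (1.11), rose, 28 and 1 adjusted over the list alone. With median-centred arrays 10 were lower and 4 higher, at a median of -0.19, and the list kept its call. Col8a1 (-3.50, SE 0.42), Col4a2 (-2.5, SE 0.32) and the matrix protease gene Mmp14 (-2.40, SE 0.26) fell. Their median was -0.92 (adjusted p = 7.89e-06, adjusted p = 0.467 with an estimated correlation). The size for Col8a1 rests on its brightest probe set, since the other 2 gave -0.10, which did not pass, and -1.12 in Q111 cells, against -1.74 and -2.93 in Q7 cells. The first of these differed between the lines in its response (1.64, adjusted p = 0.0118 over all probe sets). Mitosis genes were lower in 14 of 29 cases and Aurka (0.81) was higher, likewise adjusted over the list alone. Their median of -0.51 turned to 0.21 with median-centred arrays (camera adjusted p = 0.0052, adjusted p = 0.583 with an estimated correlation). Mki67 fell by 1.60 (SE 0.26), Cenpe by 1.46 (SE 0.21) and Kif23 by 1.26 (SE 0.16). Genes of the list actin cytoskeleton and focal adhesion were lower in 18 of 36 cases and 2 were higher, likewise adjusted over the list alone. Their median of -0.27 turned to 0.46 with median-centred arrays (adjusted p = 0.0231, adjusted p = 0.583 with an estimated correlation). Ankrd1 (-1.74, SE 0.23) and zyxin, Zyx (-1.62, SE 0.24), fell, and Tagln (1.89, SE 0.36) and Rhoa (0.54) rose. Median-centred arrays ended the calls of the mitosis list (adjusted p = 0.16, range over the alternatives 0.000585 to 0.583) and the actin list (adjusted p = 0.293, range 0.00105 to 0.583), and the latter was also lost without Q111 heat shock replicate 2 (adjusted p = 0.0878) and with the actin 3' minus 5' level as a covariate (adjusted p = 0.0719). Among the brighter genes alone, those with a mean level at or above the median, neither list was called (adjusted p = 0.122 and 0.304), nor was the interferon list (adjusted p = 0.058, range 8.5e-06 to 0.583).

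The other large rises in Q111 cells were in Eid3 (5.97, SE 0.25), P2rx7, an ATP-gated channel (5.42, SE 0.24), Ifitm5 (4.97, SE 0.29), Klb (4.97, SE 0.29) and Speer4cos (4.53, SE 1.23), each from background range. Prmt6, an arginine methyltransferase gene (-4.60, SE 0.41), Haghl (-4.59, SE 0.36), Scara3 (-4.40, SE 0.32), Zbtb22 (-4.23, SE 0.37), Cemip, which acts in hyaluronan breakdown (-4.07, SE 0.42), and the elastic fibre gene Emilin1 (-3.96, SE 0.41) fell most, with Prmt6, Scara3 and Zbtb22 ending in background range. The other probe set of Prmt6 (-0.49) and both others of Cemip (1.21, and 0.44 at a mean in background range) did not pass, nor did 1 of the other 3 of Haghl (-0.71; the rest gave -4.39 and -5.19). Another Emilin1 probe set gave -1.66. limma called 8758 genes, 3633 higher and 5125 lower, and 4879 changed at least 2-fold. The share of higher genes, 41.5%, was 82.5% with median-centred arrays. It was 33.7% with ribosomal centring and 41.2% with a further quantile normalization. Actin 3' minus 5' signal went from 0.72 ± 0.36 to 1.25 ± 0.23 along with these groups, and 4381 genes were called with it as a covariate, 32.0% of them higher. Over the 8758 genes the median size went from 1.08 to 1.03 and the median SE from 0.22 to 0.32. Replicate 3 of the heat-shocked Q111 arrays had the lowest mean correlation with its own group, 0.957. Without it and Q7 heat shock replicate 2, which deviated in the same way (r = 0.588 across genes), 8161 genes were called in Q111 and 5416 in Q7 cells.

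Across genes, the changes in the lines went together: Pearson r was 0.745 and Spearman rho 0.732 over the 18193 genes, which are not independent replicates. Of the genes called, 1486 were higher after heat shock in both lines (445.7 for independent lists) and 2631 lower in both (927.6), while 77 were higher in Q7 and lower in Q111 cells and 21 the reverse. The total least squares slope of the Q111 on the Q7 changes was 1.38 with a jackknife SE of 0.34. Leaving out each array in turn gave slopes of 1.24 to 1.55 and correlations of 0.677 to 0.777. Among 4117 genes called in the same direction in both lines, 60.2% had the larger change in Q111 cells and the median ratio was 1.10.

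**Figure D1:**
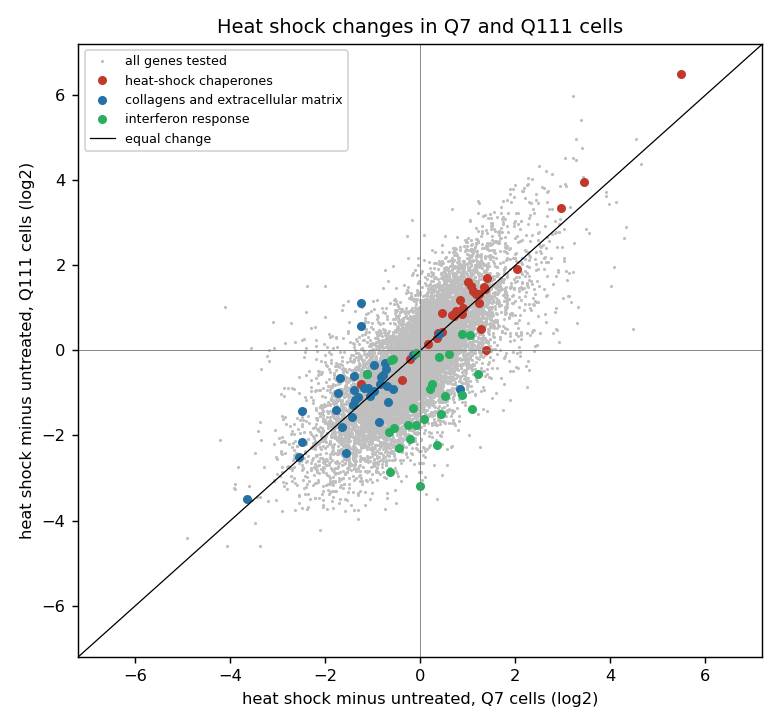
Each point is a gene, with its log2 change after heat shock in Q7 cells on the horizontal axis and in Q111 cells on the vertical axis; chaperones are red, extracellular matrix genes blue and interferon response genes green, and the line marks equal changes. The 18193 genes have a Pearson r of 0.745, chaperones lie mostly at upper right, matrix genes at lower left, and interferon genes below the line.

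The difference of the heat shock effects, tested itself, was largest mostly in genes in background range in 1 of the lines. Fbn2, fibrillin 2, fell in Q111 cells from 11.27 ± 0.08 to 7.77 ± 0.46 and was at 5.01 and 5.37 in Q7 cells (difference of effects -3.86, SE 0.51, adjusted p = 0.00316). A second Fbn2 probe set, nearly as bright, gave a difference of -2.10 and did not pass. Lrrc17 (-3.37, SE 0.45) and Oasl2 (-3.17, SE 0.40) had the same form, and Sox2ot (-3.98, SE 0.53) rose in Q7 cells and stayed in background range in Q111 cells. Apod, apolipoprotein D (-3.53, SE 0.34), and Emc9 (-3.15, SE 0.48) rose in Q7 and fell in Q111 cells, whereas Zfp386 (-3.48, SE 0.52) and Six5 (-3.24, SE 0.42) fell in Q111 cells from 8.56 and 7.59. The other Zfp386 probe set passed at -2.02, with a rise of 1.91 in Q7 and -0.11 in Q111 cells. On the positive side were Sprr2h (5.13, SE 0.42), Sorbs2 (3.90, SE 0.76), Prdm16 (3.76, SE 0.42), Tenm3 (3.64, SE 0.35), Fndc3c1 (3.52, SE 0.89), Bmp2 (3.39, SE 0.58), Adamts9 (3.29, SE 0.47) and Slc14a1 (3.19, SE 0.35). All 8 fell in Q7 cells and were in background range in Q111 cells at 33 °C, so these sizes are not firm. Of 30 genes named for this difference 10 had other probe sets above background range, and for 8 of them at least 1 did not pass. Those of Prdm16 (0.99), Dcn (1.05) and Tap1 (-0.14) were smaller, and those of Apaf1 (-1.89), Col1a2 (-1.42), Nid1 (1.35) and Pxn (-1.22) were of similar size.

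Interferon response genes had a more negative heat shock effect in Q111 than in Q7 cells: 13 of 26 passed and 0 went the other way, 15 adjusted over the list alone. The list median was -1.38 (camera adjusted p = 2.76e-09, adjusted p = 0.596 with an estimated correlation). Ifit1 differed by -2.56 (SE 0.33) and Tap1, a peptide transporter for antigen presentation, by -2.48 (SE 0.45), although another Tap1 probe set gave -0.14 and the remaining 2 were in background range. Immediate early genes had a more positive effect in Q111 cells, with 5 of 26 passing, Dusp6 (2.22, SE 0.20), Maff (1.71, SE 0.28), Myc (1.43, SE 0.28), Klf4 (1.22) and Ier3 (0.74), and 7 adjusted over the list alone. Dusp6, a phosphatase of ERK kinases, was at 10.27 and 10.22 in Q7 cells and went from 8.73 ± 0.23 to 10.90 ± 0.07 in Q111 cells. The median over members was 0.62 (adjusted p = 0.000523, adjusted p = 0.596 with an estimated correlation). Cholesterol synthesis genes had a median difference of 0.42 with 1 gene passing, Nsdhl (1.06, SE 0.24), and 3 adjusted over the list alone (adjusted p = 0.000207, adjusted p = 0.596 with an estimated correlation). Ribosome biogenesis genes had a median of 0.34 (adjusted p = 0.000413, adjusted p = 0.596 with an estimated correlation) and no member passed limma's test singly over all genes or over the list alone. With median-centred arrays 8 of 30 ribosome biogenesis genes, 7 of 20 cholesterol synthesis genes and 9 of 26 immediate early genes passed, each more positive in Q111 cells, and 9 of 26 interferon genes, each more negative.

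The list of cytosolic heat-shock chaperones and co-chaperones was not called for the difference (median 0.11, camera adjusted p = 0.0914), and Hspa1a differed by 1.0 (SE 0.31, adjusted p = 0.0863), Hspb1 by 0.51 (SE 0.21, adjusted p = 0.197) and Htt by 0.14 (SE 0.23, adjusted p = 0.773). Hspa1b differed by 0.15, Hsph1 by 0.11, Dnajb1 by 0.08 and Hsf2 by -0.22, none of which passed. The chaperone genes that did differ, the same 2 adjusted over the list alone, were Dnajb2, which rose in Q7 cells from 9.63 ± 0.12 to 11.01 ± 0.04 and was at 9.46 in Q111 cells at both temperatures (-1.38, SE 0.27, adjusted p = 0.0157), and Ahsa2, a relative of an Hsp90 activator (-0.77, SE 0.17, adjusted p = 0.0232). Dnaja4 differed by 0.37 with the probe set used, which did not pass, while one nearly as bright passed at 0.86, more positive in Q111 cells, and the last gave 1.23 without passing. With median-centred arrays the chaperone list was called (median 0.49, adjusted p = 0.0301), as it was among the brighter genes alone (adjusted p = 0.00145) and without Q7 untreated replicate 3 (adjusted p = 0.0472), over a range of 0.00145 to 0.612.

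Of the other lists called for the difference, p53 targets had a median of -0.31, which turned to 0.06 with median-centred arrays, and 1 gene passed, Apaf1 of the apoptosome (-1.53, SE 0.27); camera gave an adjusted p of 0.0428. Extracellular matrix genes had a median of 0.20, with Dcn (2.35, SE 0.32), Nid1 (1.05, SE 0.27) and Col1a2 (-1.73, SE 0.30) passing (adjusted p = 0.037). Actin cytoskeleton genes had a median of 0.15, with Tagln (2.01, SE 0.50) and Pxn, paxillin (-0.99, SE 0.26), passing (adjusted p = 0.0236). For these 3 lists the counts were the same adjusted over the list alone. Medians were 0.10 for oxidative phosphorylation (adjusted p = 0.0236), 0.18 for ATF4 and amino acid response genes (adjusted p = 0.0438), 0.11 for proteasome subunits (adjusted p = 0.0485) and 0.60 for BDNF and REST target genes linked to Huntington's disease (adjusted p = 0.0485), and 0 genes of these 4 lists passed in limma, over all genes or adjusted over the list alone. Of 23 alternatives 16 ended the call of the BDNF and REST targets, 15 that of the proteasome, 11 those of p53 targets, extracellular matrix and oxidative phosphorylation, 9 that of ATF4 and 8 that of actin. The BDNF and REST call ended with median-centred arrays (adjusted p = 0.188) and with quantile normalization (adjusted p = 0.0609), over a range of 0.0215 to 0.612. Quantile normalization ended those of oxidative phosphorylation (adjusted p = 0.0521, range 2.58e-05 to 0.612), p53 targets (adjusted p = 0.0705, range 0.00371 to 0.612) and the proteasome (adjusted p = 0.0705, range 0.000448 to 0.612), the last lost with ribosomal centring (adjusted p = 0.0575) and the replicate block (adjusted p = 0.0675) too. With the actin 3' minus 5' level as a covariate the calls of actin cytoskeleton (adjusted p = 0.0689, range 0.000148 to 0.612), extracellular matrix (adjusted p = 0.291, range 0.000266 to 0.612), oxidative phosphorylation (adjusted p = 0.136), proteasome (adjusted p = 0.268) and BDNF and REST targets (adjusted p = 0.06) ended. Among the brighter genes alone those of p53 targets (adjusted p = 0.289) and BDNF and REST targets (adjusted p = 0.329) ended. Without both heat-shocked arrays that stand apart, those of ATF4 (adjusted p = 0.0772), actin (adjusted p = 0.0601), extracellular matrix (adjusted p = 0.225), p53 targets (adjusted p = 0.084) and BDNF and REST targets (adjusted p = 0.0553) ended. Each of these 7 lists had adjusted p = 0.596 with an estimated correlation, and each lost its call without Q7 heat shock replicate 2 and without Q111 heat shock replicate 1. Over all left-out arrays the highest adjusted p was 0.289 for p53 targets, 0.175 for extracellular matrix, 0.151 for actin, 0.101 for oxidative phosphorylation, 0.259 for ATF4, 0.171 for proteasome and 0.151 for the BDNF and REST targets. Other left-out arrays ended some of these calls too, at the camera adjusted p given for each. Q7 heat shock replicate 1 ended that of the list HD-associated BDNF and REST targets (0.0691) and replicate 3 that of proteasome subunits (0.0619). Q111 heat shock replicate 2 ended those of ATF4 and amino acid response (0.0549), oxidative phosphorylation (0.0549) and proteasome subunits (0.157), and replicate 3 those of p53 targets (0.052), collagens and extracellular matrix (0.052) and BDNF and REST targets (0.0761). Q7 untreated replicate 1 ended those of collagens and extracellular matrix (0.0976), actin cytoskeleton and focal adhesion (0.0976) and BDNF and REST targets (0.102). Q7 untreated replicate 2 did so for p53 targets (0.152), collagens and extracellular matrix (0.0712), proteasome subunits (0.0642) and BDNF and REST targets (0.082), and replicate 3 for oxidative phosphorylation (0.0851), ATF4 (0.259) and proteasome subunits (0.149). Q111 untreated replicate 1 ended those of p53 targets (0.289), oxidative phosphorylation (0.0512), ATF4 (0.195), proteasome subunits (0.171) and BDNF and REST targets (0.0512), replicate 2 those of collagens and extracellular matrix (0.0791), oxidative phosphorylation (0.0624) and proteasome subunits (0.113), and replicate 3 that of BDNF and REST targets (0.0768).

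For the difference of effects limma called 1041 genes, 221 more positive and 820 more negative in Q111 cells, of 3852 with an unadjusted p under 0.05. Of the 1041, 511 were called for heat shock only in Q111, 219 only in Q7 cells and 98 in opposite directions. The share of more positive genes, 21.2%, was 62.1% with median-centred arrays. It was 19.7% with ribosomal centring and 28.8% with a further quantile normalization. Without single arrays the count ranged from 379 to 1238, and it was 500 without Q7 heat shock replicate 1, 379 without replicate 3, 590 and 574 without Q7 untreated replicates 2 and 3, and 648, 532 and 683 without Q111 untreated replicates 1, 2 and 3.

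At 33 °C interferon response genes were higher in Q111 than in Q7 cells, in 20 of 26 cases with 0 lower, and 23 adjusted over the list alone. Ifit1 was at 11.59 ± 0.32 in Q111 and 4.32 ± 0.13, in background range, in Q7 cells, Usp18 at 10.20 ± 0.64 against 3.74 ± 0.27 and the antiviral gene Rsad2 at 10.38 ± 0.14 against 4.49 ± 0.24. The median over members was 2.12 (camera adjusted p = 5.06e-28, adjusted p = 0.0817 with an estimated correlation). Microglia and macrophage markers, measured beside them, had a median difference of 0.04 and a median level of 3.62 in Q111 cells. Of these 12 markers 4 were above background range in any group. The chemokine gene Ccl5 (7.0, SE 0.56), the sodium channel gene Scn3a (7.44, SE 0.57), the transcription factor gene Zic1 (7.17, SE 0.43), Slc43a3 (6.99, SE 0.28) and thrombomodulin, Thbd (6.86, SE 0.57), were also among the largest, with Q7 levels of 2.78 to 5.16.

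Neural progenitor markers were lower in Q111 cells at 33 °C in 5 of 15 cases, Sox2 (-5.89), Pax6 (-4.59), the intermediate filament gene Nes (-3.60), Fabp7 (-2.58) and Msi2 (-1.34), and Dlx5 (1.10) was higher; 6 and 1 passed adjusted over the list alone. Sox2, a stem cell transcription factor, was at 10.60 ± 0.34 in Q7 and 4.71 ± 0.29 in Q111 cells, and the list median was -0.20 (camera adjusted p = 0.00108, adjusted p = 0.0306 with an estimated correlation). The largest negative differences were in Bex1, at 11.03 ± 0.05 in Q7 and 3.06 ± 0.38 in Q111 cells, the neural transcription factor gene Pou3f3 (-6.83, SE 0.19), the neuronal stathmin gene Stmn2 (-6.57, SE 0.39), Tenm3 (-6.41, SE 0.25), Sall1 (-6.11, SE 0.32) and the adhesion gene Cadm1 (-5.99, SE 0.22). Except for Cadm1, at 5.6, these were in background range in Q111 cells. Other probe sets gave smaller differences for Sall1 (-2.07) and, for 1 of 3, Cadm1 (-3.12). The fibroblast and mesenchymal markers had a median of 0.26, with Col1a2 (3.48) and Pdgfra (2.43) higher and Twist2 (-1.07) lower of 13, and 3 and 1 adjusted over the list alone (adjusted p = 0.0269, adjusted p = 0.0883 with an estimated correlation). That call was lost with median-centred arrays (adjusted p = 0.0506), with the BioB spike as a covariate (adjusted p = 0.0698) and with the untreated arrays alone in replicate blocks (adjusted p = 0.0578), and its alternatives ranged from 2.38e-05 to 0.137.

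**Figure D2:**
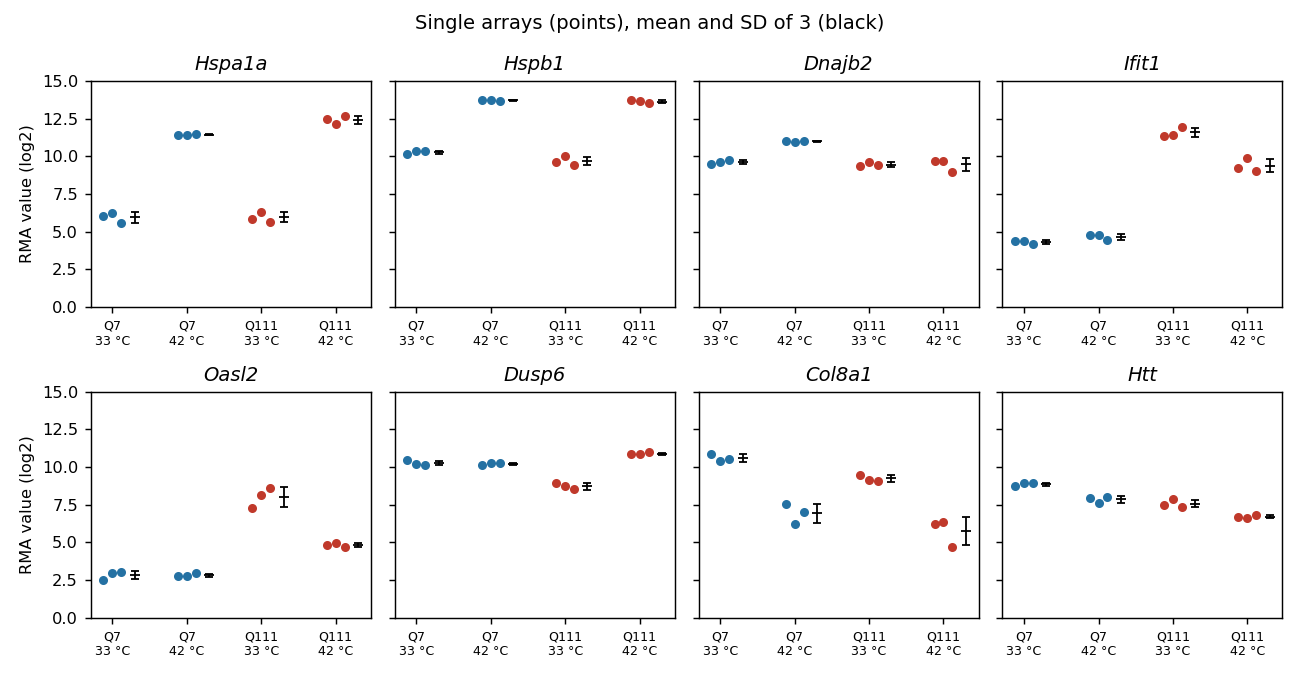
Each point is the log2 level of a gene on an array, by group, with the mean and SD of 3 arrays in black, for Hspa1a, Hspb1, Dnajb2, Ifit1, Oasl2, Dusp6, Col8a1 and Htt. Hspa1a goes from 5.96 to 11.45 in Q7 and from 5.95 to 12.43 in Q111 cells, and Ifit1 is at 4.32 in Q7 and 11.59 in Q111 cells at 33 °C.

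Extracellular matrix genes differed in both directions at 33 °C, with 11 of 35 higher and 6 lower in Q111 cells, and 15 and 10 adjusted over the list alone. Biglycan, Bgn, was higher by 3.83 (SE 0.34), Col1a2 by 3.48 (SE 0.21) and Tgfbi by 3.28 (SE 0.26). The median over members was 0.29 (camera adjusted p = 0.0231, adjusted p = 0.73 with an estimated correlation). ATF4 and amino acid response genes were lower at a median of -0.43, with 4 of 24 passing and 0 higher, the same adjusted over the list alone: Cth, cystathionine gamma-lyase (-1.95, SE 0.29), Vldlr (-1.37, SE 0.36), Nupr1 (-0.70, SE 0.12) and Ddit4 (-0.61). Their adjusted p was 2.06e-06, and adjusted p = 0.693 with an estimated correlation. Ribosome biogenesis genes had a median of -0.47 (adjusted p = 2.06e-06, adjusted p = 0.693 with an estimated correlation), with 4 of 30 lower, Wdr12 (-0.75, SE 0.18), Nop58 (-0.60, SE 0.15), Mybbp1a (-0.55, SE 0.14) and Wdr43 (-0.52), and 11 adjusted over the list alone. Autophagy genes had a median of 0.25 (adjusted p = 0.00168, adjusted p = 0.693 with an estimated correlation), with 4 of 21 higher, Gabarapl1 (0.62, SE 0.12), Map1lc3a (0.51, SE 0.12), Ctsl (0.48, SE 0.14) and Ctsb (0.42), and 8 adjusted over the list alone.

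Targets of p53 were lower in Q111 cells at 33 °C at a median of -0.25 (camera adjusted p = 0.0231, adjusted p = 0.73 with an estimated correlation). The 5 of 23 that passed, the same number adjusted over the list alone, were Cdkn1a (-1.14, SE 0.25), Psrc1 (-1.04, SE 0.26), Phlda3 (-0.93, SE 0.24), Perp (-0.91) and Aen (-0.58). The sizes for Cdkn1a and Psrc1 depend on untreated Q111 replicate 1. It was at 11.03 against 9.98 and 9.94 for Cdkn1a, and at 9.53 against 8.59 on both others for Psrc1. Cholesterol synthesis genes had a median of -0.22 (adjusted p = 0.0147, adjusted p = 0.73 with an estimated correlation) with Sc5d (-0.79, SE 0.13) and Msmo1 (-0.48, SE 0.14) lower of 20, and 1 adjusted over the list alone. The p53 call was lost without Q7 untreated replicate 1 or 3 (adjusted p = 0.14 and 0.0652) or Q111 untreated replicate 2 or 3 (adjusted p = 0.265 and 0.0514), and the cholesterol call without Q7 untreated replicate 1 (adjusted p = 0.0568). The BioB spike, a control RNA, was at 10.02 ± 0.22 in Q7 and 10.62 ± 0.54 in Q111 cells at 33 °C. As a covariate it ended both calls (adjusted p = 0.081 for p53 targets and 0.244 for cholesterol synthesis), and the actin 3' minus 5' level ended that of p53 targets (adjusted p = 0.0717). With fry neither was called (adjusted p = 0.0769 and 0.0713). Over all alternatives the ranges were 6.27e-05 to 0.762 and 0.00438 to 0.73. Of the chaperones Cryab (-0.74, SE 0.14), Hspb1 (-0.60, SE 0.15), Hspd1 (-0.57) and Cacybp (-0.48) were lower and Hspa2 (0.71, SE 0.18) higher, and 4 and 1 adjusted over the list alone, with no call for the list (median -0.08, adjusted p = 0.406). Hspa1a (-0.01), Hspa1b (0.09), Hsph1 (-0.06), Dnajb1 (0.16) and Hsf2 (-0.21) did not pass at 33 °C.

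limma called 1962 genes at 33 °C, 929 higher and 1033 lower in Q111 cells, and 1355 of them differed at least 2-fold. With the replicate number as a block, which pairs the untreated arrays, 1916 genes were called and 3600 with the untreated arrays alone, the latter a fit chosen after seeing the data. The extracellular matrix call at 33 °C was lost without Q7 untreated replicate 3 (adjusted p = 0.0652), without Q111 untreated replicate 1 (adjusted p = 0.1) and with the untreated arrays alone in replicate blocks (adjusted p = 0.148). Of 35 genes named at 33 °C 22 had other probe sets above background range, and for 7, Htt, Map1lc3a, Msmo1, Mybbp1a, Psrc1, Sc5d and Vldlr, at least 1 did not pass. The block ended the call of Ctsl (adjusted p = 0.0754), Msmo1 (adjusted p = 0.0686) and Mybbp1a (adjusted p = 0.0561) and that of the extracellular matrix list (adjusted p = 0.0601), whose adjusted p ranged over the alternatives from 0.00555 to 0.281, 0.0123 to 0.235, 0.00559 to 0.136 and 0.00741 to 0.762 in that order.

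After heat shock p53 targets were lower in Q111 than in Q7 cells in 13 of 23 cases with 0 higher, the same adjusted over the list alone. Zmat3 was lower by 1.93 (SE 0.34), Psrc1 by 1.59 (SE 0.26) and Apaf1 by 1.24 (SE 0.19). The median was -0.79 (camera adjusted p = 6.36e-05, adjusted p = 0.898 with an estimated correlation). With median-centred arrays 5 p53 targets were lower and 0 higher, at a median of -0.41, and the list kept its call. Interferon response genes were higher in 12 of 26 cases and Ifit2 (-0.77) was lower, 13 and 3 adjusted over the list alone. Their median was 0.71 (adjusted p = 5.15e-07, adjusted p = 0.898 with an estimated correlation). Cxcl10 was at 11.29 ± 0.14 in Q111 and 6.25 ± 0.91 in Q7 cells, Usp18 at 8.46 ± 0.79 against 3.65 ± 0.84 and Ifit1 at 9.38 ± 0.44 against 4.67 ± 0.21. Extracellular matrix genes were higher in 14 of 35 cases and lower in 3, Col4a1 (-0.82), Col12a1 (-1.51) and Vcan (-1.18), and 14 and 5 adjusted over the list alone. Bgn (4.27, SE 0.34), Tgfbi (3.31, SE 0.26) and Dcn (3.10, SE 0.23) led, the median was 0.08 and the mean 0.59 (adjusted p = 0.00122, adjusted p = 0.967 with an estimated correlation). Immediate early genes were higher in 7 of 26 cases, among them Egr2 (1.48, SE 0.48), Maff (1.46, SE 0.20) and Klf2 (1.42, SE 0.31), and lower in Klf4 (-0.75) and Btg2 (-0.90), and 9 and 2 adjusted over the list alone. Their median was 0.32 (adjusted p = 0.0132, adjusted p = 0.967 with an estimated correlation), and the call was lost without Q111 heat shock replicate 1 (adjusted p = 0.189) and with fry (adjusted p = 0.11; range over the alternatives 0.000237 to 0.967).

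Hspa1a was higher in Q111 cells after heat shock by 0.99 (SE 0.22, adjusted p = 0.00733), as were the co-chaperone gene Bag3 (0.98, SE 0.21) and Dnaja4 (0.58), and Dnajb2 (-1.55, SE 0.19), Cryab (-0.76) and Ahsa2 (-0.49) were lower, 3 and 3 of 30 over all genes and adjusted over the list alone. The list was not called (median 0.05, camera adjusted p = 0.563), nor were Hspb1 (-0.09), Hspa1b (0.24), Hsph1 (0.04), Dnajb1 (0.24) and Hsf2 (-0.43) by limma. The other 2 Hspa1b probe sets passed, at 0.68 and 0.67, and the others of Dnaja4 gave 0.93 and 0.97. Those of Dcn (1.30) and Egr2 (1.27) did not pass, and another Sall1 probe set gave -2.49. The largest differences were in the mitochondrial co-chaperone gene Dnajc15 (6.35, SE 0.43), Thbd (6.29, SE 0.57), Ccl5 (6.28, SE 0.56) and Zic1 (6.08, SE 0.43), and in Bex1 (-7.80, SE 0.19), Sox2 (-6.99, SE 0.36), Pou3f3 (-6.40, SE 0.19) and Sall1 (-6.13, SE 0.32). Zic1 in Q7 cells, and the 4 negative genes in Q111 cells, were in background range. For the 4 positive genes heat-shocked Q7 replicate 1 was above the other Q7 arrays, with Thbd at 7.29 against 4.45 and 4.72, so these sizes depend on it. On the other heat-shocked Q7 arrays all 4 genes were in background range, at 4.81 or lower. The cause was not tested. The neural progenitor markers were lower in 7 of 15 cases with 0 higher, and 7 and 1 adjusted over the list alone. The list median was -0.43 (adjusted p = 0.0331, adjusted p = 0.0949 with an estimated correlation), a call lost without Q7 or Q111 heat shock replicate 2 (adjusted p = 0.0664 and 0.0759) and without both heat-shocked arrays that stand apart (adjusted p = 0.1; range over the alternatives 2.22e-07 to 0.227). Astrocyte markers were higher in 4 of 9 cases, the glutamate transporter gene Slc1a3 (2.68), Aldoc (1.44), Glul (1.18) and Aldh1l1 (0.70), with 0 lower and 5 adjusted over the list alone. The median was 1.18 (adjusted p = 0.00347, adjusted p = 0.0949 with an estimated correlation).

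In all, limma called 4018 genes after heat shock, 1197 higher and 2821 lower in Q111 cells, and 2293 differed at least 2-fold. Of those called at 33 °C, 471 were higher (61.1 for independent lists) and 623 lower (160.2) at both temperatures; the comparisons use different arrays. The share of higher genes, 29.8%, was 72.6% with median-centred arrays. It was 31.3% with ribosomal centring and 36.4% with a further quantile normalization. Without Q7 heat shock replicate 1 the count was 2594 and without replicate 3 it was 2597.

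**Figure D3:**
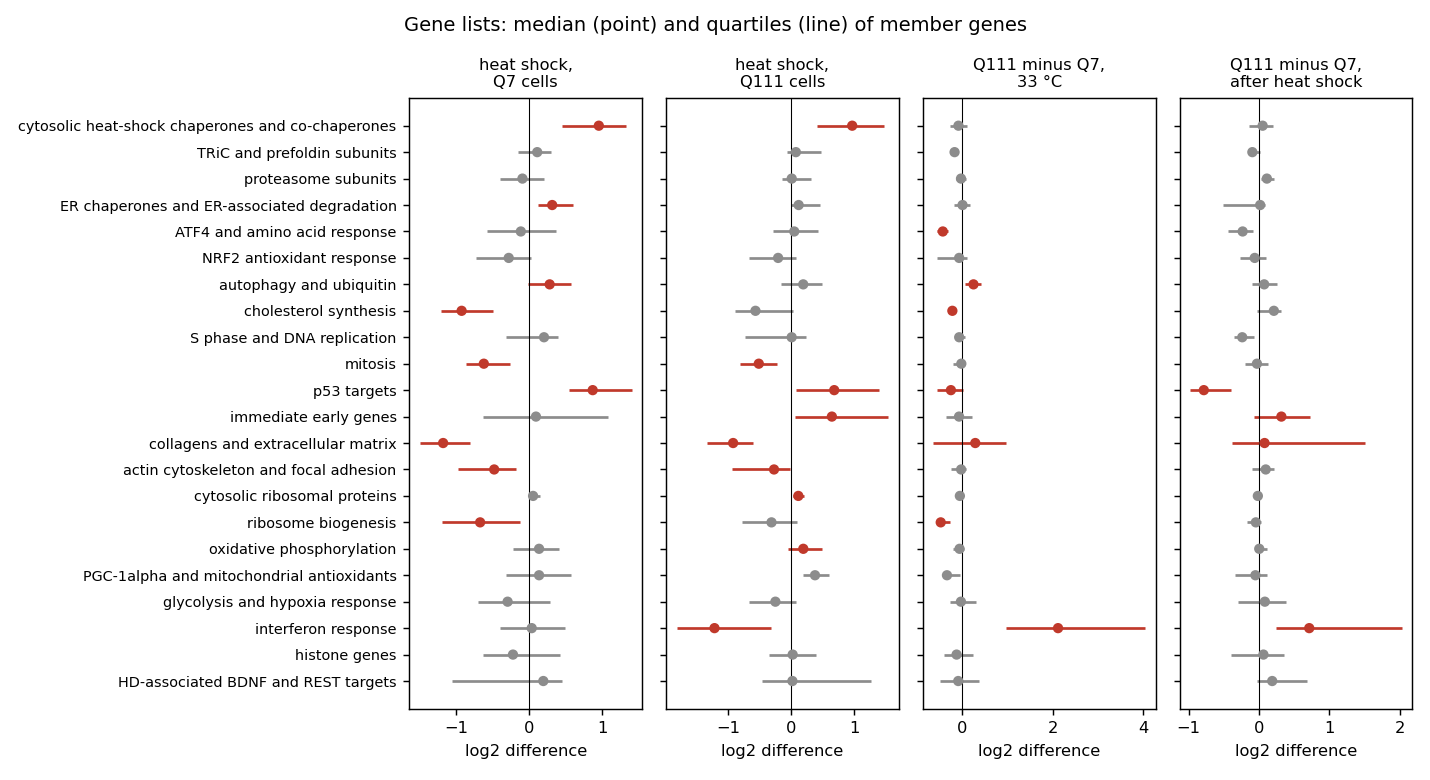
For each of the 22 gene lists, a point marks the median log2 difference of its members and a line their quartiles, in 4 panels for 4 comparisons; red marks lists that camera called at an adjusted p under 0.05 with the preset correlation and grey the others. The interferon list lies at 2.12 for the lines at 33 °C. The difference of the heat shock effects is not drawn.

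Several lists had no call in any comparison of 2 groups with the preset correlation and the arrays as deposited. TRiC and prefoldin subunits had medians of 0.11 in Q7 and 0.08 in Q111 cells after heat shock (camera adjusted p = 0.444 and 0.157), proteasome subunits -0.09 and 0.01 (adjusted p = 0.57 and 0.378), NRF2 antioxidant genes -0.28 and -0.21 (adjusted p = 0.0633 and 0.224), PGC-1alpha and mitochondrial antioxidant genes 0.13 and 0.38 (adjusted p = 0.293 and 0.0602), glycolysis and hypoxia genes -0.30 and -0.25 (adjusted p = 0.178 and 0.375), histone genes -0.22 and 0.02 (adjusted p = 0.889 and 0.577) and the BDNF and REST target genes 0.19 and 0.02 (adjusted p = 0.889 and 0.377). With median-centred arrays camera called the TRiC and prefoldin list (14 of 14 genes higher) and the proteasome list (28 of 34 higher) in Q111 cells, and the proteasome list between the lines after heat shock (19 of 34 higher in Q111 cells). The PGC-1alpha list was called in Q111 cells when arrays were quantile normalized again (5 of 12 higher), and these 3 lists were called there among the brighter genes alone. fry, which does not compare a list with other genes, called the NRF2 and PGC-1alpha lists after heat shock in both lines, glycolysis in Q7 and TRiC in Q111 cells, and the BDNF and REST targets between the lines at 33 °C. With single arrays left out, calls appeared for PGC-1alpha in Q111 cells (without Q111 heat shock replicate 3 or untreated replicate 2), NRF2 in Q7 cells (without Q7 untreated replicate 1), TRiC at 33 °C (without Q111 untreated replicate 3) and the proteasome between the lines after heat shock (without Q111 heat shock replicate 3). The last was also called with the BioB spike as a covariate. For the BDNF and REST targets in Q7 cells the mean was -0.18, opposite in sign to the median. ATF4 and amino acid response genes had medians of -0.12 and 0.05 after heat shock (adjusted p = 0.911 and 0.224), and a mean of 0.02 in Q7 cells. S phase genes in Q111 cells had a median of 0.01 and a mean of -0.16, and camera ranked them upward (adjusted p = 0.773). Between the lines at 33 °C, markers of neurons had a median of -0.0005 (adjusted p = 0.58), of striatal projection neurons -0.02 (adjusted p = 0.58), of the oligodendrocyte lineage 0.05 (adjusted p = 0.863), of microglia 0.04 (adjusted p = 0.863) and of endothelium 0.02 (adjusted p = 0.863), and sex-linked genes had 0.04 (adjusted p = 0.863). Means of the oligodendrocyte (-0.03) and endothelial (-0.21) markers were opposite in sign to their medians. Above background range in any group were 4 of 10 oligodendrocyte, 4 of 12 microglia, 3 of 9 endothelial and 1 of 4 sex-linked genes. Median levels of the neuron and striatal markers at 33 °C, 4.35 to 4.68, were in background range too. Medians near 0 can thus hide differences within that range.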

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

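The tests of array scaling, of the 2 arrays that stand apart, of RNA 3' bias, of microglia, of matched lists and of background range, and the comparison of spreads between splits, were chosen after the results were seen, and the comparison of sizes within the 3' bias test only after its count was known, and that of directions after its value was seen. The T antigen test was written before, but the weight given to members that go both ways was set after its value was seen.

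The heat shock effects of the lines differed in 1041 genes by limma's interaction test, and 820 of them were more negative in Q111 cells. Leaving out both heat-shocked arrays that stand apart gave 1413 genes, 30.0% of them positive, which argues against those arrays as the source of the direction. Centring arrays on their medians, which adds the same amount to each gene of an array, raised the positive share from 21.2% to 62.1%. It moved the median difference over genes from -0.0065 to 0.37. Centring on ribosomal protein genes gave 19.7% and a further quantile normalization 28.8%. Of these scalings only median centring turned the direction, so it could come from scaling only if the median of genes is the right reference. Among the brighter genes alone 12.9% of 868 genes called were positive, 112 against 756 negative. The median difference over the brighter genes was -0.18, so the direction also went with signal level. The SD over probe sets was 2.74 in heat-shocked Q111 arrays and 2.83 to 2.89 in the other groups. The cause was not tested. With the actin 3' minus 5' level as a covariate 22.1% of 407 genes called were positive, 90 against 317 negative. Of the 407 genes 397 were among the 1041 first called. Adjusting for this measure did not turn the direction. Its slope rests on the spread within groups of 3 arrays and the measure moved with heat shock, so RNA 3' bias is not settled. Calls were lost to a wider error. Over the genes first called the median size went from 1.53 to 1.57 and the median SE from 0.31 to 0.36. Over all probe sets the array median was 5.66 ± 0.05 and 5.63 ± 0.06 in Q7 cells, untreated and heat-shocked. In Q111 cells it was 5.63 ± 0.07 and 5.69 ± 0.04. Median centring moved the median change over genes from 0.0026 to 0.35 in Q7 and from -0.0182 to 0.71 in Q111 cells. These values argue against the median of genes as the right reference. A shift shared by all genes was not measured.

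Interferon response genes were higher in Q111 cells at 33 °C and had a more negative heat shock effect there, with a median difference of effects of -1.38; of the 20 called higher at 33 °C, 10 were in background range in Q7 cells at a temperature and could hardly fall there. Microglia or macrophages among the Q111 cells are argued against by the median difference of their markers, 0.0402, and a median marker level of 3.62. Of the 12 markers 4 were above background range in any group. A fall that any gene higher in Q111 cells would share was checked with 10000 lists of other such genes matched on the 33 °C difference. These lists had a median of -0.87 and the 20 genes a median of -1.67, and 0.13% of the lists were as low. Genes of a list were drawn independently, while the interferon list lost its call when the correlation between its genes was estimated. The share can thus be too small and does not decide whether the fall is shared. The 10 genes above background range in Q7 cells at both temperatures had a median of -1.52, so the negative difference was not confined to genes in that range. All 20 were chosen as higher at 33 °C on arrays that also enter the difference, which by itself lowers it. The 909 other genes chosen so had a median of -0.62. Background range as the whole cause is thus not decided by these 10 genes. Of lists matched on the Q7 level too 0.21% were as low as the 20 genes. Their members were drawn independently as well, so that share can be too small. The huntingtin allele and other differences between the lines stay open and untested, with 1 line per genotype.

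Targets of p53 rose and mitosis genes fell after heat shock in Q7 cells, and the mitosis median in Q111 cells went from -0.51 to 0.21 with median-centred arrays. STHdh lines carry a temperature-sensitive SV40 large T antigen, and its loss at 42 °C could release p53 and lower S phase genes. Against the bound written before the test, the S phase median in Q7 cells was 0.20 (0.12 to 0.20 without single arrays) and not below 0. That bound counts against the loss as written, yet it was wrong in reading a median over members that went both ways, 8 higher and 5 lower with quartiles of -0.32 and 0.40, so the loss and heat shock itself cannot be told apart, with no group at 42 °C free of a possible loss.

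In the comparisons of 2 groups the 3 against 3 arrays make 10 splits, too few for a share under 0.05. Only 1 split, the real one, called as many genes in each. It called 5525 for heat shock in Q7 cells, 8758 in Q111 cells, 1962 for the lines at 33 °C and 4018 after heat shock. The highest other was 0 in all 4. Every other split mixes the groups compared, so their difference enters the residual spread and holds down the calls. These counts of 0 are thus no evidence for the real grouping. For the difference of effects 100 splits of the 12 arrays were drawn and 2 called as many genes as the real one, itself included. The other splits mix the groups, so that heat shock enters the residual spread (median SD 0.44 against 0.26 in the real split) and 93 of 99 called 0 genes. That draw neither excludes chance nor shows it. The highest other, 3330, set 5 untreated arrays and 1 heat-shocked array against the rest, a structure of the samples close to heat shock itself.

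Single genes were picked out by the test of the difference of heat shock effects, Q111 minus Q7. Positive differences were 5.13 for Sprr2h, 3.90 for Sorbs2, 3.76 for Prdm16, 3.64 for Tenm3, 3.52 for Fndc3c1, 3.39 for Bmp2, 3.29 for Adamts9, 3.19 for Slc14a1, 2.35 for Dcn, 2.22 for Dusp6, 2.01 for Tagln, 1.71 for Maff, 1.43 for Myc, 1.06 for Nsdhl and 1.05 for Nid1. Negative ones were -3.98 for Sox2ot, -3.86 for Fbn2, -3.53 for Apod, -3.48 for Zfp386, -3.37 for Lrrc17, -3.24 for Six5, -3.17 for Oasl2, -3.15 for Emc9, -2.56 for Ifit1, -2.48 for Tap1, -1.73 for Col1a2, -1.53 for Apaf1, -1.38 for Dnajb2, -0.99 for Pxn and -0.77 for Ahsa2.

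By the same test camera called 10 further lists beside interferon, by median 0.62 for immediate early genes, 0.60 for BDNF and REST targets, 0.42 for cholesterol synthesis, 0.34 for ribosome biogenesis, 0.20 for extracellular matrix, 0.18 for ATF4 response, 0.15 for actin cytoskeleton, 0.11 for proteasome, 0.10 for oxidative phosphorylation and -0.31 for p53 targets, the last 0.06 with median-centred arrays. With an estimated correlation each of the 11 lost its call (adjusted p = 0.596). Of the 10 further lists all but immediate early genes, cholesterol synthesis and ribosome biogenesis also lost it without Q7 heat shock replicate 2 and without Q111 heat shock replicate 1, with highest adjusted p over left-out arrays of 0.101 to 0.289.

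Control probe sets for the short repeats B1 and B2, whose RNA polymerase III transcripts are known to rise in heat-shocked mouse cells, were outside the genes tested and were higher after heat shock. The first B2 probe set went from 8.30 ± 0.46 to 9.63 ± 0.38 in Q7 cells (1.33) and from 8.42 ± 0.23 to 10.27 ± 0.40 in Q111 cells (1.85). The second B2 probe set was 0.29 and 0.42 higher and the B1 probe set 0.89 and 1.33 higher in Q7 and Q111 cells. In each case all 3 heat-shocked arrays lay above all 3 untreated arrays, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 can give.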

How the results depend on the processing

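Leaving out the arrays that stand apart, both covariates, the block over untreated arrays alone and the combined list setting were chosen after seeing the data. For 192 values of named genes there were 5147 alternative values. Of these 4868 kept direction and side of the threshold, 237 lost the call, 25 gained one and 17 changed sign, none of them called. With median-centred arrays Hsf2 was 0.15 for the difference of effects and Hspb1 0.29 after heat shock. Hspb1 was 0.0031 with array weights. Hspa1a at 33 °C was 0.0172 with ribosomal centring and 0.0251 with quantile normalization. Htt was -0.0504 for the difference without the 2 arrays, Hsf2 0.21 at 33 °C with the BioB covariate and Hsph1 -0.005 after heat shock with the actin covariate. With arrays left out in turn Hsf2 ranged from -0.50 to 0.0418 for the difference and from -0.47 to 0.0775 at 33 °C. At 33 °C Hspa1a ranged from -0.21 to 0.14 and Hsph1 from -0.17 to 0.0107. The calls of Msmo1 (20 alternatives), Pxn (18), Egr2 (17), Ctsl (16) and Nid1 (15) were lost most often. Levels in background range make folds infirm, and probe sets near the top of the range, such as Hspb1 after heat shock, can understate a change.

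Counts are in the order heat shock in Q7, in Q111, difference, lines at 33 °C and after heat shock. An adjusted p under 0.01 gave 3498, 5719, 224, 1255 and 2239 genes, fewer by construction. Array weights, whose fit did not converge, gave 9293 for Q7, 3406 for the difference and 8938 after heat shock. The brighter genes alone gave 5567 for Q111 and 1046 at 33 °C, with fewer genes tested. Median centring gave 13331 for Q111 and 6291 after heat shock, and only the groups compared 2674 after heat shock. The actin covariate gave 436, 4381 and 407 for Q7, Q111 and the difference. It left median sizes of the called genes at 0.98 (from 1.04), 1.03 (from 1.08) and 1.57 (from 1.53), and raised their median SE to 0.43, 0.32 and 0.36. Beyond the stricter threshold, fewer genes tested and this wider error, the cause was not tested. Arrays left out in turn gave 4060 to 6598, 7205 to 8572, 379 to 1238, 1470 to 2401 and 2594 to 4152 genes. The difference had 500 without Q7 heat shock replicate 1 and 379 without replicate 3. It had 590 and 574 without Q7 untreated replicates 2 and 3, and 648, 532 and 683 without Q111 untreated replicates 1, 2 and 3. The lines after heat shock had 2594 and 2597 without Q7 heat shock replicates 1 and 3.

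The replicate block gave 5496, 8706, 1110, 1916 and 4046 genes, and 3600 at 33 °C with the untreated arrays alone. Of the groups compared directly, only the untreated arrays had every same-number r over 0.1. Those of Q111 heat-shocked and Q7 untreated arrays, which meet only in the difference, were 0.165, 0.222 and 0.263. Between the heat-shocked groups same-numbered arrays had r of 0.345, -0.497 and -0.315, and each of these was below the highest r with another number. Apart from calls named with the lines at 33 °C, the block ended those of Tagln for the difference (adjusted p = 0.0546, range over the alternatives 0.0034 to 0.101) and Egr2 after heat shock (adjusted p = 0.0518, range 0.000677 to 0.149). It also ended that of the proteasome subunits for the difference (adjusted p = 0.0675, range 0.000448 to 0.612). It changed no other call of a named gene or called list.

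The gene lists called were 9, 9, 11, 7 and 4, and left-out arrays gave 9 to 10, 9 to 11, 4 to 10, 5 to 8 and 3 to 6. The difference had 4 without Q7 heat shock replicate 2 or Q111 heat shock replicate 1, 7 without Q7 untreated replicate 2 and 6 without Q111 untreated replicate 1. An estimated correlation left 1, 1, 0, 0 and 0 lists, and 0 in every comparison without the 2 arrays. For each called list the highest adjusted p came with an estimated correlation. fry gave 14 for Q111 and 1 for the difference. For the difference, quantile normalization gave 7, leaving out the 2 arrays 6 and the actin covariate 6. After heat shock, brighter genes gave 9, median centring 7 and the BioB covariate 7. The cause was not tested.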

Other observations

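After heat shock in Q111 cells 8 of 15 neuron markers were higher and 0 lower, among them the synaptic gene Snap25 (2.48) and Stmn2 (1.42), although the list was not called (median 0.67, camera adjusted p = 0.0874). Of 15 striatal projection neuron markers 5 were higher, the dopamine receptor gene Drd1 (2.35), Arpp21 (2.03), the transcription factor gene Bcl11b (1.82), Tac1 (1.11) and the cannabinoid receptor gene Cnr1 (0.93), and 1 was lower (list median 0.14, adjusted p = 0.186). Each gene named here started in background range, as Drd1 did at 4.58 ± 0.69. Changes in Q111 cells also went with level, with a median of -0.36 among the brighter genes and -0.0182 over all genes. Of genes called, 1627 were higher and 3940 lower among the brighter genes, against 3633 and 5125 over all. Dimmer genes thus rose more often, and the rises of these markers cannot be told apart from that general pattern. In Q7 cells 2 neuron markers were higher and the list median was 0.37 (adjusted p = 0.737). By the test of the difference itself limma called Tac1 (1.75) and Bcl11b (1.29) and 0 of the neuron markers.

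In protein degradation, 2 genes went opposite ways in the lines. The ubiquitin ligase gene Syvn1, which acts on misfolded proteins of the endoplasmic reticulum, rose in Q7 (0.66) and fell in Q111 cells (-0.79), with a difference of -1.45 (SE 0.29, adjusted p = 0.0183). Ulk1, the kinase that starts autophagy, rose in Q7 (0.57) and fell in Q111 cells (-0.98), with a difference of -1.55 (SE 0.20, adjusted p = 0.00316). These genes were chosen after their values were seen, and their lists were not called for the difference (adjusted p = 0.2 each).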
